A study of Oreochromis niloticus with 6 samples.

How the data were processed

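Total RNA of gill from genetically improved farmed tilapia (Nile tilapia) was extracted with Trizol and made into Illumina libraries, per the labels' protocols. The 6 libraries fall into 2 groups of 3 by their treatment label, control and hypoxia stress. Per the labels, dissolved oxygen was 5 mg/L in control tanks and was lowered within 30 min to 1.02 ± 0.10 mg/L in the exposed tanks, and gills were sampled at 96 h. The labels disagree on the layout. One text describes 3 tanks per group with 15 fish each, 90 in all, and another describes 4 replicates per group and 30 fish per 500 L tank. Which tank or fish a library came from, and whether fish were pooled, is not given in the sources used here.

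One table of the series was used, with 1 FPKM column per library over 40538 rows, and no column of values was left unmatched to a library. The FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) were made by the authors with HISAT and StringTie, per the submitters' processing notes; versions, genome build and annotation release are not given in the sources used here. Of the rows, 37062 carry StringTie locus identifiers (MSTRG) and 3476 carry Ensembl gene identifiers. Such assembled loci can merge neighbouring genes or split a gene, and near-identical copies of teleost genes can share reads, so values of duplicated symbols and of neighbouring loci are uncertain. In 417 rows the name holds more than 1 gene, and these matched no list. Gene names came from the table. The reference gene table supplied for names (assembly O_niloticus_UMD_NMBU) matched 0 of the identifiers and was not used, and positions are not reported. An exact 0 can be a failed estimate: 389 tested rows were listed at 0 in at least 1 library and at 10 FPKM or more in another, and 43 called rows held a 0.

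FPKM is not a count, so no count model was fitted. Values were taken to log2(FPKM + 1), and the 25111 rows with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, two-sided, without covariates, with Benjamini-Hochberg adjustment over these rows at 0.05. Every adjusted p of a gene is from this limma test, and log2 changes are labelled hypoxia minus labelled control on the log2(FPKM + 1) scale. Of the tested rows 11671 carry no gene symbol. The sequencing depth is unknown. Steps of the lowest values (under 0.15 FPKM) gave each library's depth relative to hypoxia replicate 1, as 1.21, 1.09 and 1.21 for control replicates 1 to 3 and 1.06 and 1.07 for hypoxia replicates 2 and 3. The precision of a value is therefore given only as the spread over 3 libraries.

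Before the data were examined, 25 lists of genes by function and 12 lists of cell type markers were fixed and matched to rows by symbol, allowing for the copy endings of bony fish. Lists of at least 5 rows were tested with limma's camera (preset inter-gene correlation 0.01, and an estimated correlation as an alternative), adjusted over the 37 lists. The counts adjusted over the list alone use the same gene p-values, adjusted within the list. Genes are named by a rule fixed at the same time: the 10 largest increases and 10 largest decreases with a symbol, an adjusted p under 0.05 and groups that do not overlap; the 3 members of each list with the smallest p, or at most 2, as values, where none passes; and the copies of hif1a, epas1, egln3, vegfa and ldha. Rows that complete a count of 5 or fewer, smchd1, and further loci of acads, akt3b, ctsl.1, hmgcra, IDH2, IDH3G, mmp13a and pard3 were named after their values were seen. Some genes that this rule names are not reported here.

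The gene fit was tested on simulated data with the means and spreads of the 25111 rows. It recovered 24 of 100 rows changed by 1 on the log2 scale and 51 of 100 changed by 2, with 3 false calls among 24911 unchanged rows. The changed rows were a smaller share than the 1699 rows called in the real data. The Benjamini-Hochberg cutoff depends on that share, so these recoveries are not the power of the real test. In the camera test of the 37 lists, the interferon response list shifted by 0.5 was called (adjusted p = 2.62e-09). Of the lists that share no row with it, 0 were called. The simulated rows were drawn independently of each other, so this run cannot show how often lists of correlated genes are called falsely. The alternatives were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, the TPM scale (each library scaled to the same sum), median-of-ratios scaling, quantile normalization, robust empirical Bayes, library weights, the replicate number as a block, an estimated correlation for lists, and each library left out in turn. After seeing the data, 2 were added: the hemoglobin rows (12, found through the table's gene ontology and names) left out with the libraries rescaled, and rows of the same symbol summed for the list test. KEGG sets from the table's own annotation were also tested after seeing the data.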

Results

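RNA-seq libraries were made from the gills of genetically improved farmed tilapia, a selectively bred strain of Nile tilapia (Oreochromis niloticus). Of the 6 libraries, 3 were labelled control and 3 were labelled hypoxia, the latter from fish sampled 96 h after the dissolved oxygen of their water was lowered with nitrogen. The comparison asks which gill transcripts differ after this exposure. The labels do not say from which tank or fish each library came or whether fish were pooled, so the p-values below measure only the spread between these samples. Expression was given as FPKM, with summed values of 438405 to 483691 per library over 40538 rows. The number of sequenced fragments is unknown. The spacing of the lowest values put the other libraries at 1.06 to 1.21 times the depth of hypoxia replicate 1. Pearson correlations of log2(FPKM + 1), taken across genes, which are not independent replicates, were 0.853 to 0.901 within groups and 0.80 to 0.854 between them. No 2 libraries shared more than 1 identical value above 0. Because genes known to be induced through the hypoxia-inducible factor (HIF) went against the group labels, as given below, the groups are called the libraries labelled control and the libraries labelled hypoxia, and every direction rests on those labels.

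In the libraries labelled hypoxia, the lists of fatty acid and cholesterol synthesis, HIF target genes and the unfolded protein response lay lower, and those of interferon response, extracellular matrix, cartilage and bone, skeletal muscle and the cell cycle lay higher, each with some of its members past the threshold. None of these list calls held with an estimated correlation (adjusted p = 0.252 to 0.360). Of 25111 rows tested with limma, 870 were higher and 829 were lower at a Benjamini-Hochberg adjusted p under 0.05, together 6.77% of the rows. Among these, 478 rose and 443 fell by at least 1 on the log2(FPKM + 1) scale, which understates the change of low genes. All 1699 called rows had groups that did not overlap, and 8328 of all tested rows (33.2%) did, where chance gives 10%. Only 1005 of the called rows carried a gene symbol. Rescaling changed the balance of the calls, to 595 higher and 949 lower on the TPM scale and to 700 higher and 1029 lower with median-of-ratios scaling. Leaving out 1 library gave 428 higher and 602 lower rows without control replicate 1, 161 and 194 without control replicate 2, 248 and 253 without control replicate 3, 104 and 151 without hypoxia replicate 1, 783 and 792 without hypoxia replicate 2, and 130 and 160 without hypoxia replicate 3.

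Of the 37 gene lists fixed before the data were examined, 19 passed an adjusted p of 0.05 in a camera test with a preset inter-gene correlation of 0.01, 6 of them upward and 13 downward relative to all other rows. None of the 37 passed with an estimated correlation, where 4 had an unadjusted p under 0.05 (fatty acid and cholesterol synthesis, antioxidant and NRF2, HIF target genes, and unfolded protein response). The list tests therefore rest on the preset correlation, and the adjusted p with an estimated correlation is given for each called list.

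**Figure D1:**
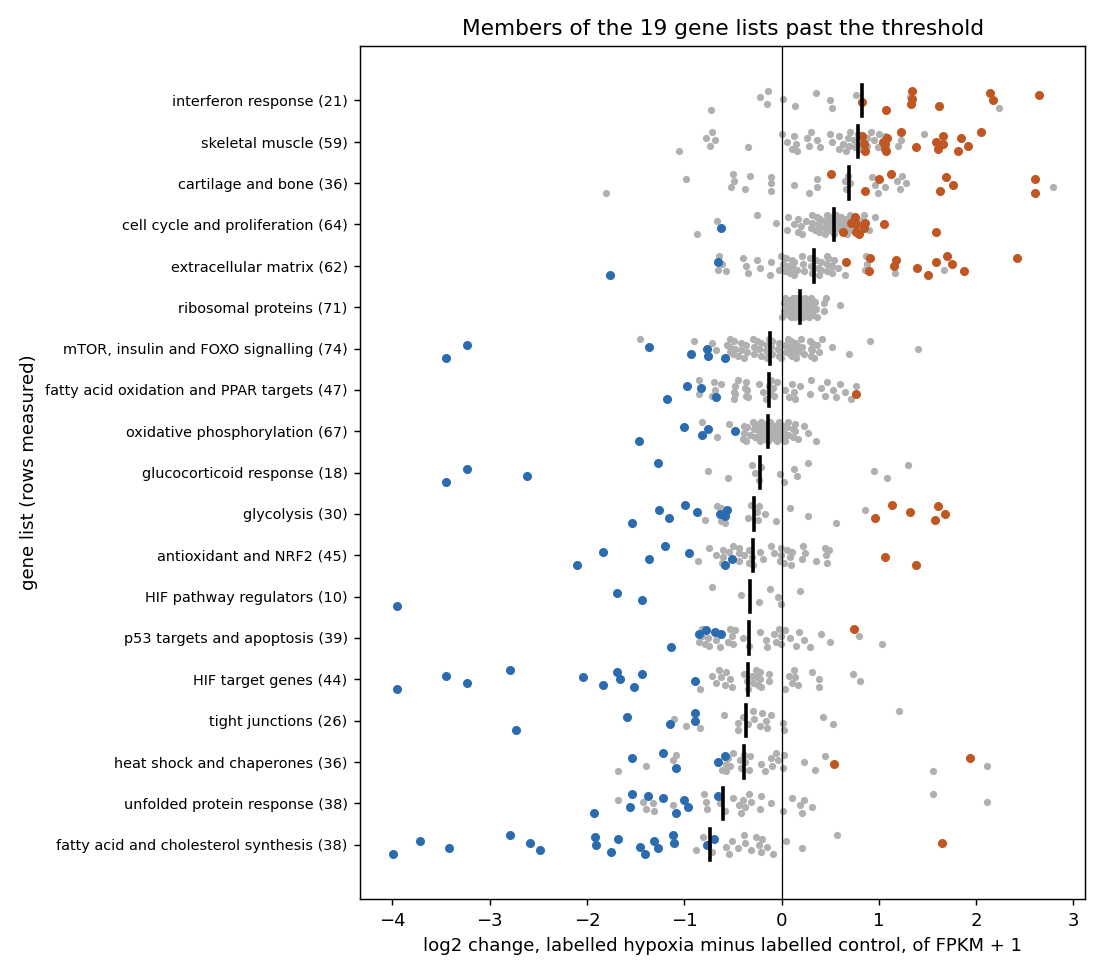
Log2 change of FPKM + 1 (labelled hypoxia minus labelled control, horizontal axis) of each measured member of the 19 called gene lists (vertical axis, with the rows measured). Orange and blue points passed an adjusted p of 0.05 upward and downward, gray points did not, bars are list medians, and rows listed at 0 in all libraries of a group are not drawn. Medians ran from -0.74 for fatty acid and cholesterol synthesis to 0.83 for interferon response.

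Some HIF target genes, 11 of 44 rows, were lower in the libraries labelled hypoxia. In the camera test with an estimated correlation the list did not pass (adjusted p = 0.286). egln3, a prolyl hydroxylase that marks HIF for degradation and is itself a HIF target, was at 69.8 ± 37.04 FPKM (SD, n = 3) in the libraries labelled control and 3.25 ± 0.699 FPKM (n = 3) in those labelled hypoxia, a 21.5-fold difference of means (log2 change -3.95 ± 0.36 SE, adjusted p = 0.00923). Both loci of the mTOR inhibitor ddit4 fell, from 19.4 ± 9.29 to 1.04 ± 0.147 FPKM (MSTRG.18305) and from 45.4 ± 24.3 to 3.47 ± 3.13 FPKM (DDIT4 MSTRG.5326, adjusted p = 0.0309). In MSTRG.5326 hypoxia replicate 2 lay at 7.05 FPKM and the others labelled hypoxia at 1.23 and 2.14, so the 13.1-fold difference became 26.9-fold without it, and the call was lost with any of the other 5 libraries left out (adjusted p = 0.0576 to 0.109). The lipid droplet protein plin2 fell from 19.02 to 5.96 FPKM and heme oxygenase HMOX1 from 18.5 to 4.44 FPKM. Of the 44 measured rows of the HIF target list, 11 fell, none rose and 33 did not pass. Adjusted over the list alone, 17 fell and 2 rose. The list median was -0.35, with a camera adjusted p of 3.69e-07 and an adjusted p = 0.286 with an estimated correlation. The number that fell was 7 without control replicate 2 or hypoxia replicate 1 and 6 without hypoxia replicate 3, and 1 row rose without control replicate 1.

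Of the 10 rows of HIF pathway regulators, 3 fell and none rose (4 and 0 adjusted over the list alone). They were egln3, the asparagine hydroxylase hif1an (10.2 ± 0.902 to 3.14 ± 0.470 FPKM) and the prolyl hydroxylase egln2 (23.5 to 6.39 FPKM), which also belong to the HIF target list. That membership was fixed by symbol and does not show that hif1an or egln2 is induced by HIF. The list of regulators had a camera adjusted p of 0.00237 and an adjusted p = 0.286 with an estimated correlation. The HIF alpha subunits did not pass the test. hif1aa was at 44.5 ± 10.4 and 32.7 ± 5.34 FPKM (adjusted p = 0.279) and epas1b at 36.1 ± 5.16 and 36.0 ± 6.95 FPKM (adjusted p = 0.981). The lactate dehydrogenase gene ldha was at 8.25 ± 1.38 and 5.02 ± 1.13 FPKM (adjusted p = 0.112). Copies of vegfa were not analysed here.

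**Figure D2:**
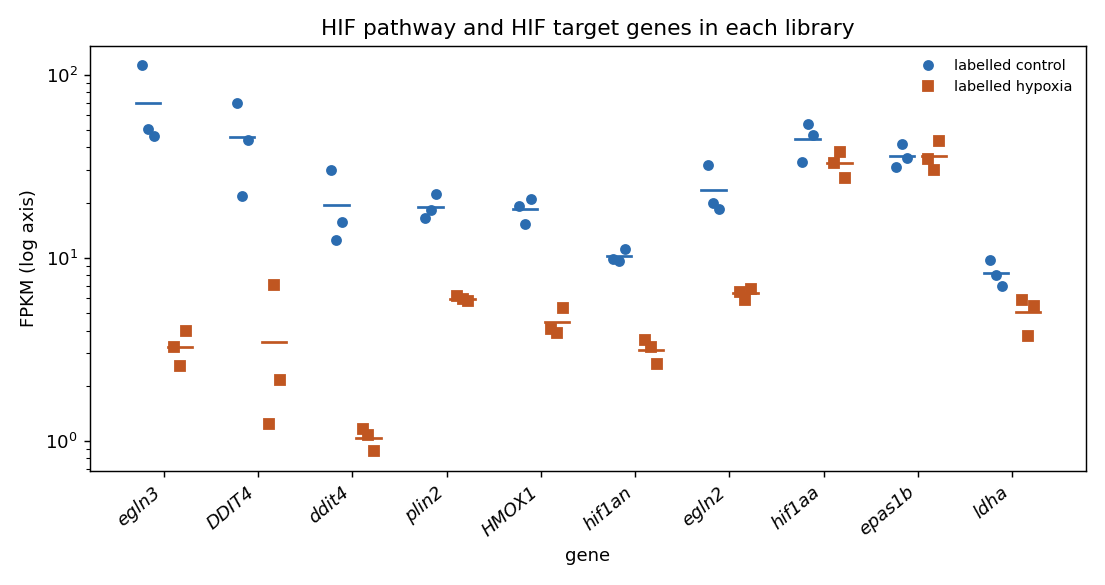
FPKM on a log axis (vertical) of 10 HIF pathway and HIF target rows (horizontal) in each of the 3 libraries labelled control (blue circles) and the 3 labelled hypoxia (orange squares), with group means as bars. The groups do not overlap for egln3, DDIT4 (MSTRG.5326), ddit4 (MSTRG.18305), plin2, HMOX1, hif1an, egln2 and ldha, of which ldha did not pass the test, whereas hif1aa and epas1b overlap.

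The fatty acid and cholesterol synthesis list had the lowest median of the 37 lists. msmo1, which removes methyl groups from sterol precursors, fell from 67.8 ± 10.9 to 3.65 ± 2.29 FPKM (18.6-fold, log2 change -3.99 ± 0.36 SE, adjusted p = 0.00923). The rate-limiting reductase hmgcra (MSTRG.665) fell from 24.7 ± 2.90 to 1.01 ± 0.617 FPKM (24.5-fold, adjusted p = 0.00433) and the squalene epoxidase sqlea from 15.8 to 0.65 FPKM (24.3-fold). Without hypoxia replicate 2 these differences were 28.3-fold for msmo1, 37.7-fold for hmgcra and 61.5-fold for sqlea. Another hmgcra locus (MSTRG.666) was at 9.02 and 7.23 FPKM (adjusted p = 0.485). The low-density lipoprotein receptor ldlrb fell from 74.3 to 21.3 FPKM. tm7sf2, a sterol reductase outside the list, fell from 15.3 to 0.685 FPKM. Of 38 measured rows in the fatty acid and cholesterol synthesis list, 18 fell, 1 rose and 19 did not pass (26 fell and 2 rose adjusted over the list alone). The row that rose was dgat2, of triglyceride synthesis, from 0.0547 to 2.43 FPKM (44.5-fold, and 68.2-fold without control replicate 3), named after its values were seen. The list had a median of -0.74, a camera adjusted p of 3.22e-15 and an adjusted p = 0.252 with an estimated correlation. Leaving out 1 library gave 11 (without hypoxia replicate 3) to 17 (without hypoxia replicate 2) rows that fell and none that rose.

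Some glycolytic enzymes rose and others fell. The skeletal muscle list, which shares pgam2 with the glycolysis list, was higher in the same libraries (18 of 59 rows rose, median 0.79, adjusted p = 0.360 with an estimated correlation). Whether muscle in the pieces of gill accounts for the glycolytic rows that rose was not tested. The aldolase aldoaa rose from 29.4 ± 3.67 to 96.4 ± 11.1 FPKM (adjusted p = 0.00923), while its relative aldocb fell from 224 to 92.6 FPKM and gapdhs, a glyceraldehyde-3-phosphate dehydrogenase, fell from 137 to 61.0 FPKM. Of 30 rows, 6 rose and 8 fell (8 and 12 adjusted over the list alone). The list had a median of -0.28, a camera adjusted p of 0.0480 and an adjusted p = 0.428 with an estimated correlation. That call was lost in 11 of 17 alternatives with a preset correlation, including a minimum mean of 5 FPKM (adjusted p = 0.424), the TPM scale (0.0571), median-of-ratios scaling (0.0675), quantile normalization (0.240), library weights (0.0515), the hemoglobin rows left out (0.0533), and the fits without control replicate 2 (0.0977), hypoxia replicate 1 (0.0513), hypoxia replicate 2 (0.0920) or hypoxia replicate 3 (0.0544), in a range of 0.0159 to 0.424 over all 17. The numbers that rose and fell were 4 and 5 without control replicate 1, 4 and 3 without control replicate 2, 3 and 4 without control replicate 3, 2 and 1 without hypoxia replicate 1, 6 and 5 without hypoxia replicate 2, and 2 and 2 without hypoxia replicate 3.

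Among other genes of energy metabolism, the muscle glycogen phosphorylase pygma rose from 7.43 to 21.8 FPKM, and the glycogen synthase gys1 (15.7 to 3.59 FPKM), the gluconeogenic pck2 (27.8 to 5.53 FPKM), fbp1a and fbp1b fell. This made 1 higher and 4 lower of 15 rows of gluconeogenesis and glycogen (3 and 5 adjusted over the list alone), with a camera adjusted p of 0.0683. The TCA cycle list held 31 rows, among them cytosolic enzymes outside the cycle such as idh1. In this list idh1 (119 to 51.7 FPKM), IDH2 (MSTRG.335, 15.0 to 5.22 FPKM) and the citrate synthase cs fell and IDH3G (MSTRG.26304) rose (1 and 4 adjusted over the list alone, camera adjusted p = 0.0651). The other 2 tested IDH2 loci did not pass (adjusted p = 0.126 and 0.781), and the first of them, MSTRG.3798, was at 52.7 and 65.6 FPKM. A second idh3g locus (MSTRG.13303) was at 13.3 and 13.7 FPKM (adjusted p = 0.870). Of 67 rows of oxidative phosphorylation, 5 fell and none rose, with the same counts adjusted over the list alone. They were cytochrome c cycsb (137 ± 15.3 to 49.6 ± 9.41 FPKM in MSTRG.12140, and a second locus, MSTRG.1447), the cytochrome oxidase subunits cox6b1 (436 to 218 FPKM) and cox5aa, and uqcrc2b. That list had a median of -0.14, a camera adjusted p of 8.77e-05, an adjusted p = 0.360 with an estimated correlation and an adjusted p of 0.716 after quantile normalization, in a range of 9.37e-07 to 0.716 over its alternatives with a preset correlation. Its lower rows numbered 0 without control replicate 2, 1 without hypoxia replicate 1 or hypoxia replicate 3, 2 without control replicate 1 or control replicate 3, and 3 without hypoxia replicate 2. In the gluconeogenesis and glycogen list 1 or 2 rows fell with any 1 library left out, and in the TCA cycle list none then rose and 1 fell without control replicate 2, control replicate 3, hypoxia replicate 1 or hypoxia replicate 3.

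Of 47 rows of fatty acid oxidation and PPAR targets, the nuclear receptor pparg (17.98 to 8.62 FPKM) and the oxidation enzymes acads (MSTRG.2797, 11.99 to 4.62 FPKM), HADHA and acadm fell, and the fatty acid binding protein fabp11a rose from 13.5 to 23.5 FPKM. The neighbouring acads locus (MSTRG.2796) was at 12.01 and 8.98 FPKM (adjusted p = 0.441). These 4 lower and 1 higher rows became 5 and 1 adjusted over the list alone. The list had a camera adjusted p of 0.0362 and an adjusted p = 0.322 with an estimated correlation. It was lost after quantile normalization (0.0954), without control replicate 2 (0.0702) and without hypoxia replicate 2 (0.0563), in a range of 0.0185 to 0.0954. None of its rows passed without control replicate 2, hypoxia replicate 1 or hypoxia replicate 3, and 1 fell without control replicate 3 and 2 without hypoxia replicate 2. In the 3 paragraphs on energy metabolism and in those that follow, rows outside the fixed rule (such as fbp1a, fbp1b, IDH3G, uqcrc2b, HADHA and acadm) were named after their values were seen, to complete a count of 5 or fewer.

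Some interferon response genes, 9 of 21 rows, were higher in the libraries labelled hypoxia. In the camera test with an estimated correlation their list did not pass (adjusted p = 0.322). rsad2 (MSTRG.20063), an antiviral enzyme, rose from 20.2 ± 4.21 to 95.7 ± 25.9 FPKM (log2 change 2.17 ± 0.25 SE, adjusted p = 0.0139), isg15 (MSTRG.17902), a ubiquitin-like modifier, from 6.46 ± 1.36 to 49.9 ± 27.3 FPKM, usp18, which removes that modifier, from 6.49 to 33.0 FPKM, and the transcription factor irf3 from 2.15 to 8.60 FPKM. The antiviral helicase gene znfx1 and parp12b, outside the list, rose from 2.40 to 22.1 FPKM and from 2.43 to 21.9 FPKM. Of 21 rows, 9 rose and none fell (11 and 0 adjusted over the list alone). The list had a median of 0.83, a camera adjusted p of 1.30e-05 and an adjusted p = 0.322 with an estimated correlation. The number that rose was 1 without control replicate 2, and the count was 5 without control replicate 1 and 2 without control replicate 3, hypoxia replicate 1 or hypoxia replicate 3. The list mean lay between 3.47 and 3.96 on the log2 scale in the libraries labelled control and between 4.503 and 4.83 in those labelled hypoxia.

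The other immune lists did not pass the camera test. Of 38 rows of inflammatory cytokines and NF-kB, the collagenase mmp13a (MSTRG.15477, 4.82 to 0.705 FPKM), the cytokine signalling inhibitor socs3b (18.6 to 3.79 FPKM) and ptgs2b of prostaglandin synthesis fell, and tlr3 (MSTRG.15276), tnfa and ccl19a.1 rose (11 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.598). Of 20 rows of antigen presentation, the class II invariant chain cd74b (MSTRG.1327, 1081 ± 105 to 2681 ± 245 FPKM) and a locus of the protease ctsl.1 (MSTRG.20003, 2.71 to 6.56 FPKM) rose and the chaperone calr fell (3 and 4 adjusted over the list alone). The other 3 tested ctsl.1 loci did not pass (adjusted p = 0.157 to 0.860). The median of this list was -0.03, its mean 0.09 and its test direction downward (adjusted p = 0.868). None of 15 rows of complement and coagulation passed, also not over the list alone (camera adjusted p = 0.145); the coagulation starter f3a was at 33.1 and 22.7 FPKM (adjusted p = 0.0606) and c5 at 5.99 and 3.70 FPKM (adjusted p = 0.0748). No row of the inflammatory list passed without control replicate 2 or hypoxia replicate 1, and none of its rows rose without control replicate 3 or hypoxia replicate 3. In the antigen presentation list 1 row rose without control replicate 2, control replicate 3, hypoxia replicate 1 or hypoxia replicate 3.

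Of 40 rows of T cell and NK cell markers, eomesb (0.968 to 3.73 FPKM), the kinase zap70 (7.96 to 17.3 FPKM), CD247 and a granzyme locus, GZMA MSTRG.16949, rose, and another GZMA locus, MSTRG.16944, fell (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0683). Of 13 rows of B cell and plasma cell markers, irf4a and irf4b rose (4 higher and 1 lower over the list alone, adjusted p = 0.204). Of 19 macrophage and dendritic cell rows, the growth factor receptor csf1ra (3.31 to 9.65 FPKM) and zbtb46 (MSTRG.2187) rose (2 higher and 1 lower over the list alone, adjusted p = 0.650). Of 20 granulocyte rows, LECT2 (8.80 to 1.47 FPKM), mmp13a (MSTRG.15477) and nccrp1 fell (0 higher and 3 lower over the list alone, adjusted p = 0.395). No row of the T cell and NK cell list passed without control replicate 2, hypoxia replicate 1 or hypoxia replicate 3, and 1 rose without control replicate 1 or control replicate 3. In the B cell list none passed with 1 library left out, apart from 1 without hypoxia replicate 2. No macrophage and dendritic cell row passed without control replicate 2 or hypoxia replicate 3 and 1 passed without control replicate 3 or hypoxia replicate 1, and 1 granulocyte row fell without control replicate 2 or hypoxia replicate 1.

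Of the unfolded protein response list, the chaperone calr fell from 125 ± 15.8 to 41.6 ± 3.48 FPKM (log2 change -1.56 ± 0.13 SE, adjusted p = 0.00923), sdf2l1 from 31.5 to 15.7 FPKM and the stress transcription factor atf3 from 28.2 to 10.3 FPKM. Of 38 rows, 9 fell and none rose (19 and 1 adjusted over the list alone). The median was -0.61, with a camera adjusted p of 4.65e-08 and an adjusted p = 0.286 with an estimated correlation. The number that fell was 3 without control replicate 2, control replicate 3 or hypoxia replicate 1 and 4 without hypoxia replicate 3. In the heat shock and chaperone list of 36 rows, the reticulum chaperones HSPA5 (MSTRG.9553, 145 to 48.7 FPKM) and hsp90b1 (151 to 65.0 FPKM) fell with dnajc3a and dnajc3b. The unfolded protein response list also holds all of these. Outside that overlap dnajb1b fell, and hsp90aa1.1 (0.443 to 4.61 FPKM) and dnaja2 (MSTRG.448) rose. These 5 lower and 2 higher rows became 11 and 2 adjusted over the list alone. The camera adjusted p was 3.55e-04, with an adjusted p = 0.286 with an estimated correlation, and no row of this list fell past the threshold without control replicate 2, control replicate 3 or hypoxia replicate 1, while 1 did without hypoxia replicate 3 and 3 without hypoxia replicate 2.

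In the antioxidant and NRF2 list of 45 rows, 7 rows fell, among them HMOX1 and tkta (MSTRG.33375), of the pentose phosphate pathway (16.95 to 3.11 FPKM), and prdx5 (MSTRG.16238) and gpx3 rose (11 lower and 3 higher adjusted over the list alone). The median was -0.29, the camera adjusted p 9.53e-04 and the adjusted p = 0.252 with an estimated correlation. The number that fell was 2 without control replicate 2 or hypoxia replicate 3 and 3 without control replicate 3 or hypoxia replicate 1. Of 39 rows of p53 targets and apoptosis, gadd45ab (22.2 to 12.6 FPKM), gadd45aa, rrm2b, fadd and CASP6 (MSTRG.18612) fell and GADD45B (MSTRG.6606) rose from 2.50 to 4.85 FPKM (16 lower and 5 higher adjusted over the list alone). The camera adjusted p was 0.00113 and the adjusted p = 0.322 with an estimated correlation. No row of this list passed without control replicate 2, control replicate 3, hypoxia replicate 1 or hypoxia replicate 3, and 3 fell without control replicate 1 and 2 without hypoxia replicate 2.

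Of 74 rows of mTOR, insulin and FOXO signalling, 8 fell and none rose (9 and 1 adjusted over the list alone), among them both ddit4 loci and klf6a (21.96 to 12.5 FPKM). An akt3b locus (MSTRG.21180) was listed at 3.16, 4.43 and 2.28 FPKM in the libraries labelled control and at 0 in all 3 labelled hypoxia, while a neighbouring akt3b locus (MSTRG.21181) was at 3.06 and 3.002 FPKM (adjusted p = 0.970). The camera adjusted p was 0.0310 and the adjusted p = 0.286 with an estimated correlation. The call was lost with a minimum mean of 5 FPKM (0.205), without control replicate 1 (0.0537) and without hypoxia replicate 3 (0.0523), in a range of 0.0133 to 0.205. Its lower rows numbered 1 without control replicate 2, hypoxia replicate 1 or hypoxia replicate 3 and 3 without control replicate 3. Of 18 glucocorticoid response rows, both ddit4 loci, the chaperone fkbp5 (104 ± 24.96 to 16.3 ± 4.65 FPKM) and the phosphatase dusp1 fell (4 lower and 1 higher adjusted over the list alone). Its camera adjusted p was 0.0472 and its adjusted p = 0.286 with an estimated correlation. This call was lost in 8 of 17 alternatives with a preset correlation, including the fits without control replicate 1 (0.132), control replicate 3 (0.0734) or hypoxia replicate 2 (0.155), a minimum mean of 5 FPKM (0.0947), quantile normalization (0.152), library weights (0.113) and summed symbols (0.110), in a range of 0.00984 to 0.155, and 2 of its rows fell without control replicate 1, control replicate 2, control replicate 3 or hypoxia replicate 1.

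Of 38 MAPK and immediate early rows, 6 fell and none rose (6 and 3 adjusted over the list alone), including atf3, klf6a and the growth factor hbegfa (14.2 to 7.29 FPKM). The median of the list was 0.01, its mean -0.12 and its test direction downward (camera adjusted p = 0.327). Of 41 circadian rows, the repressor nfil3 fell from 3.17 to 1.33 FPKM (none adjusted over the list alone, camera adjusted p = 0.166). No circadian row passed with any 1 library left out, and 1 (without control replicate 2) to 3 (without control replicate 1, control replicate 3 or hypoxia replicate 2) rows of the MAPK list then fell.

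Among cell cycle genes, the spindle protein nusap1 rose from 11.99 ± 2.21 to 25.7 ± 0.881 FPKM (adjusted p = 0.0183), the microtubule regulator STMN1 from 10.8 to 35.0 FPKM and the checkpoint kinase ttk from 3.24 to 6.69 FPKM. Of 64 rows of the cell cycle list, 10 rose and 1 fell (30 and 1 adjusted over the list alone). The row that fell was rrm2b, a p53-induced ribonucleotide reductase subunit that matched the list through rrm2. The median was 0.54, with a camera adjusted p of 3.48e-10 and an adjusted p = 0.352 with an estimated correlation. The number that rose was 0 without hypoxia replicate 1 or hypoxia replicate 3, 5 without hypoxia replicate 2, 1 without control replicate 2 and 2 without control replicate 1 or control replicate 3, and 4 rose on the TPM scale and 5 with median-of-ratios scaling. None of 71 ribosomal protein rows passed singly or over the list alone, and the list median was 0.19. Its camera adjusted p was 6.18e-06, with an adjusted p = 0.510 with an estimated correlation and an adjusted p of 0.277 after quantile normalization, in a range of 4.91e-09 to 0.277. rpl38 was at 982 ± 99.8 and 1350.1 ± 108 FPKM (adjusted p = 0.0747).

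Among genes of the extracellular matrix, the type I collagen gene col1a1 rose from 40.7 ± 6.09 to 139.8 ± 18.7 FPKM (log2 change 1.76 ± 0.15 SE, adjusted p = 0.00923) and col1a2 from 33.5 to 90.0 FPKM. Of 62 extracellular matrix rows, 12 rose and 2, the collagenase mmp13a (MSTRG.15477) and the protease inhibitor timp2a, fell (18 and 3 adjusted over the list alone; camera adjusted p of 4.32e-04, adjusted p = 0.360 with an estimated correlation). A second mmp13a locus (MSTRG.29708) was at 3.19 and 5.13 FPKM (adjusted p = 0.126). col10a1b, a collagen of hypertrophic cartilage, rose from 32.8 ± 2.63 to 209 ± 52.3 FPKM (6.36-fold, adjusted p = 0.00896), its copy col10a1a from 18.6 to 66.0 FPKM, col11a1b from 3.76 to 14.6 FPKM and the cartilage link protein hapln1a from 2.51 to 18.4 FPKM. Of 36 cartilage and bone rows, 9 rose and none fell (11 and 2 over the list alone; camera adjusted p of 0.00109, adjusted p = 0.338 with an estimated correlation). Matrix rows that rose numbered 3 without control replicate 2, 4 without control replicate 3, 2 without hypoxia replicate 1 and 6 without hypoxia replicate 3. Cartilage and bone rows that rose numbered 3 without control replicate 3, 4 without control replicate 2, hypoxia replicate 1 or hypoxia replicate 3, and 5 without hypoxia replicate 2.

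Among skeletal muscle genes, the myosin light chain MYL2 rose from 11.1 ± 0.325 to 42.1 ± 8.09 FPKM (adjusted p = 0.00923), the myosin heavy chain myh7ba from 1.41 to 6.24 FPKM and the muscle phosphoglycerate mutase pgam2, which the glycolysis list also holds, from 28.5 to 89.7 FPKM. Of 59 muscle rows, 18 rose and none fell (39 and 5 over the list alone). The median was 0.79, with a camera adjusted p of 3.48e-10 and an adjusted p = 0.360 with an estimated correlation. The number that rose was 3 without hypoxia replicate 3, 10 without hypoxia replicate 2, 4 without control replicate 1 or hypoxia replicate 1, 9 without control replicate 2 and 5 without control replicate 3.

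**Figure D3:**
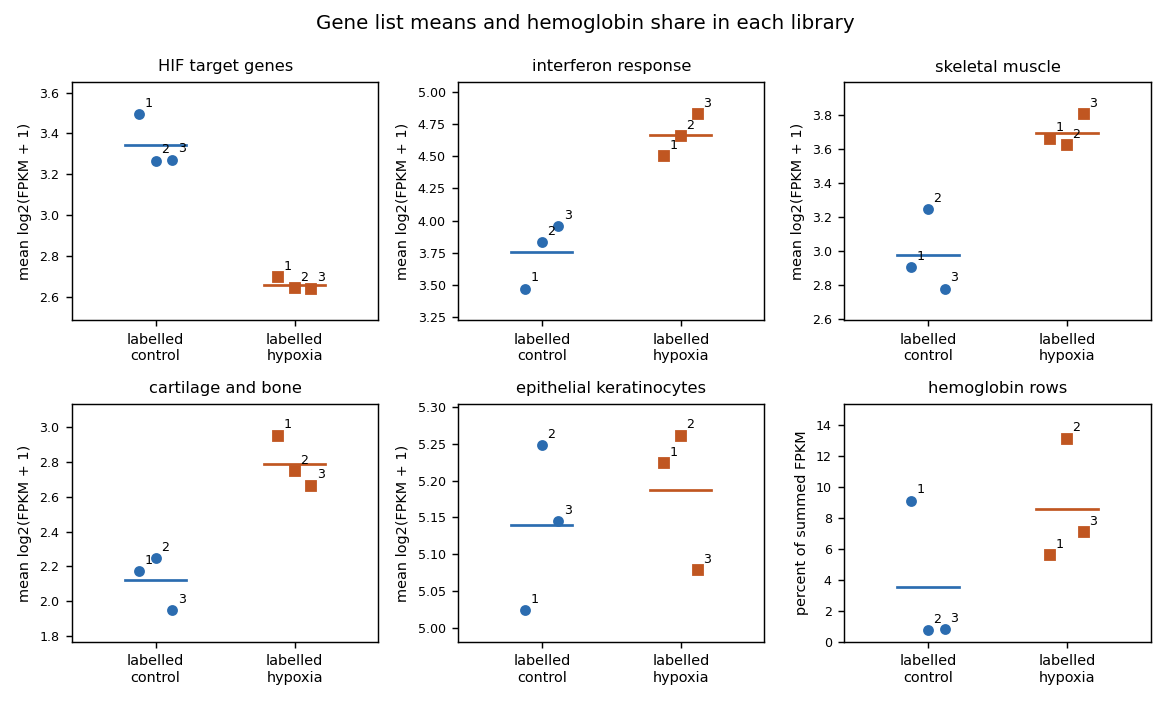
Mean log2(FPKM + 1) over the rows of 5 gene lists, and the 12 hemoglobin rows as a percentage of summed FPKM (vertical axes), in the 3 libraries labelled control (blue circles) and the 3 labelled hypoxia (orange squares), numbered by replicate, with group means as bars; the axes of the list means do not start at 0. The groups do not overlap for HIF target genes, interferon response, skeletal muscle, and cartilage and bone, whereas the epithelial markers overlap and control replicate 1 (9.11%) lies among the hemoglobin shares of the libraries labelled hypoxia.

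Blood content differed between the libraries. The 12 hemoglobin rows held 9.11%, 0.736% and 0.834% of the summed FPKM in control replicates 1 to 3 and 5.62%, 13.1% and 7.07% in hypoxia replicates 1 to 3. With these rows left out and the libraries rescaled, an alternative chosen after the data were seen, 866 rows were higher and 905 lower, and 19 lists passed. Of 18 red blood cell rows, both loci of the transferrin receptor tfr1b fell (31.6 to 8.69 FPKM in MSTRG.2440 and 63.5 to 21.8 FPKM in MSTRG.2439), with 2 lower and 1 higher over the list alone. This receptor is also found on other dividing and iron-requiring cells. The most abundant hemoglobin rows carry no symbol of the red blood cell list, so its test does not cover them. The median of the list was 0.23, its mean 0.05 and its test direction downward (camera adjusted p = 0.606). No row of this list passed with 1 library left out, apart from the case without control replicate 1, where 2 fell and 1 rose.

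Among tight junction genes, the claudin cldne (MSTRG.32269) fell from 564 ± 50.5 to 189.6 ± 39.8 FPKM (adjusted p = 0.0130), the polarity gene pard6a from 38.6 to 16.9 FPKM and the junction adaptor tjp3 from 37.2 to 19.7 FPKM, and cldn1 and a pard3 locus (MSTRG.12287) fell as well (7.71-fold for pard3, and 4.79-fold without control replicate 1). The other 2 tested loci named pard3 did not pass (adjusted p = 0.773 and 0.155). These 5 of 26 tight junction rows fell and none rose (8 and 0 over the list alone). The median was -0.37, with a camera adjusted p of 4.94e-05 and an adjusted p = 0.286 with an estimated correlation. The number that fell was 0 without control replicate 2, 1 without control replicate 3 or hypoxia replicate 3 and 2 without hypoxia replicate 1. Of 54 ionocyte and ion transport rows, 1 rose, the ammonia transporter rhbg, from 160.1 to 269 FPKM, and 1 fell (0 higher and 1 lower over the list alone, camera adjusted p = 0.288). No row of the ionocyte list passed without control replicate 2, control replicate 3, hypoxia replicate 1 or hypoxia replicate 3, and 3 fell without hypoxia replicate 2.

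Of 36 epithelial keratinocyte rows, the transcription factor elf3 fell from 96.1 to 52.2 FPKM (5 higher and 3 lower over the list alone, camera adjusted p = 0.417), and keratin krt15 was at 211 and 294 FPKM (adjusted p = 0.0542). None of 29 pillar and endothelial cell rows (adjusted p = 0.936), 12 smooth muscle and pericyte rows (0.204) or 8 mucous cell rows (0.498) passed singly, and over the list alone 0, 2 and 0 rows were higher and 0, 2 and 0 were lower. The mucous cell gene agr2 was at 62.0 ± 1.93 and 181 ± 90.2 FPKM (adjusted p = 0.0698). Of 13 neuroepithelial and nerve rows, the myelin gene mbpb rose from 3.38 to 7.51 FPKM (4 higher over the list alone). The median of this list was -0.01, its mean 0.36 and its test direction upward (camera adjusted p = 0.198). No epithelial row passed without control replicate 2, control replicate 3, hypoxia replicate 1 or hypoxia replicate 3, and no nerve row without control replicate 2, hypoxia replicate 1 or hypoxia replicate 3.

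The largest increases among rows with a gene symbol, beyond those above, were in the transglutaminase tgm8 (MSTRG.25175, 0.288 ± 0.0829 to 14.6 ± 5.52 FPKM, log2 change 3.53 ± 0.30 SE, adjusted p = 0.00923), nmrk2, a nicotinamide riboside kinase (0.307 to 9.16 FPKM, 29.8-fold, and 49.5-fold without control replicate 3), the septin sept9a (MSTRG.19521, 6.05 to 52.4 FPKM), METTL4 (MSTRG.2328, 2.36 to 24.4 FPKM) and caspa, a fish inflammatory caspase (MSTRG.22433, 1.00 to 12.1 FPKM). The neighbouring locus smchd1, named after its values were seen, moved with METTL4 (log2 change 2.39), so the assignment of reads between them is uncertain. The largest decreases beyond those above were in the adhesion gene ncam3 (323 ± 55.9 to 24.3 ± 4.14 FPKM, 13.3-fold, adjusted p = 0.00325), C19orf12 (MSTRG.624, 119 ± 106 to 6.98 ± 2.44 FPKM, adjusted p = 0.0299, 17.1-fold and 8.32-fold without control replicate 1) and the glycyl-tRNA synthetase gars (MSTRG.2244, 39.2 ± 25.3 to 2.59 ± 1.31 FPKM, adjusted p = 0.0405). Of the 119 named rows past the threshold, 37 had a symbol that other tested rows also carry, and for 29 of these at least 1 such row did not pass, so a named locus does not stand for every copy. All 119 kept their direction in every alternative run, and 35 also kept an adjusted p under 0.05 with each of the 6 libraries left out in turn.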

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

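The hemoglobin and summed-symbol alternatives were chosen after the data were seen. The 870 higher and 829 lower rows became 519 and 539 without a filter on low values, where 40538 rows were tested, and 1412 and 1289 with library weights, of which 1690 were among the 1699. With the replicate number as a block they became 0 and 2, with 5110 rows at an unadjusted p under 0.05 in limma, and the list calls of glycolysis (adjusted p = 0.0605) and glucocorticoid response (0.0757) were lost. The block leaves fewer residual degrees of freedom than the 4 of the main fit, so the drop in calls does not by itself show pairing. The labels do not say whether the numbers pair the libraries. Deviations of same-numbered libraries from their group means correlated at -0.056, -0.044 and -0.116, and by these deviations no library correlated best with its own number. Such values, taken across genes that are not independent, show no pairing but cannot exclude it. With 1 library left out, 104 to 783 rows were higher and 151 to 792 lower, with fewer samples in the fit. Both extremes come from the libraries labelled hypoxia (replicate 1 and replicate 2 left out). Under the remaining alternatives the counts were within 1.5 times the main ones. The 19 lists became 0 with an estimated correlation, 14 after quantile normalization and 16 to 20 with 1 library left out, and 17 to 22 otherwise. Apart from the estimated correlation, 13 of the 19 passed in every alternative run, while fatty acid oxidation, glucocorticoid response, glycolysis, mTOR, oxidative phosphorylation and ribosomal proteins did not.

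Of the 147 named rows, the log2 change of epas1b (-0.01 as reported) turned to 0.11 after quantile normalization and, with 1 library left out, lay between -0.15 and 0.11, above 0 without hypoxia replicate 2 (0.11), control replicate 2 (0.10) and hypoxia replicate 1 (0.01). Its adjusted p was 0.718 to 0.981 in these, and the cause was not tested. No other direction turned. Of the 119 that passed, 86 also passed in each alternative they were tested in that kept all 6 libraries, the block aside (125 of the 147 reached the minimum mean of 5 FPKM), and the adjusted p of the rest lay at up to 0.0993. The number losing the threshold was 31 without control replicate 1, 78 without control replicate 2, 65 without control replicate 3, 76 without hypoxia replicate 1, 34 without hypoxia replicate 2 and 73 without hypoxia replicate 3. Depth in fragments is unknown, so no limit of detection can be given for low rows.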

Other observations

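Sets taken from the KEGG annotation in the table, tested with camera after the data were seen, add groups that share some genes with the fixed lists. Of 185 sets of 15 to 300 rows, 20 passed (6 upward, 14 downward) with the preset correlation and 0 with an estimated one. Aminoacyl-tRNA biosynthesis was lower in the libraries labelled hypoxia (44 rows, 4 lower and 0 higher, median -0.39, adjusted p = 4.79e-05, and adjusted p = 0.654 with an estimated correlation), as were N-glycan biosynthesis (40 rows, 3 lower and 0 higher, median -0.39, adjusted p = 3.20e-04, and 0.654) and biosynthesis of unsaturated fatty acids (23 rows, 5 lower and 0 higher, median -0.37, adjusted p = 0.00176, and 0.654). DNA replication was higher (42 rows, 2 higher and 0 lower, median 0.26, adjusted p = 0.0288, and adjusted p = 0.724 with an estimated correlation).

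In what follows, the tests on exchanged labels, dilution, muscle makeup and immune cells were chosen only after the result was seen; those on scaling and on other splits were not. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1699 rows and the highest other 12, and it called 19 lists and the highest other 13, so 1 of the 10 splits reached each real value.

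Of the called HIF target genes, all 11 were lower in the libraries labelled hypoxia, with a median log2 change of -1.84, although low oxygen is known to induce genes such as egln3 and ddit4. The 11 include hif1an and egln2, for which list membership alone does not show induction by HIF. Scaling between libraries does not account for the lower values, since all 11 stayed lower past the threshold after quantile normalization. Dilution of the gill epithelium by muscle and cartilage would lower epithelial markers about as much as these 11, but the lower quartile of the marker changes was -0.35, above -1.84. This argues only against an even dilution of the epithelium. The 11 were selected for passing, and single markers moved apart (log2 change -0.86 for elf3, and 0.47 for krt15, which did not pass). The median of all 44 rows of the HIF target list was -0.35, against a median of 0.23 for the 36 epithelial rows. By this measure the epithelial markers did not fall with the list. The quartiles of the lists overlap (-0.85 to -0.09 for HIF targets and -0.35 to 0.46 for epithelial markers). For the list as a whole, dilution of a part of the epithelium therefore stays open (camera adjusted p = 0.286 with an estimated correlation). Exchanged group labels stay open: the lowest library labelled control lay 0.57 above the highest labelled hypoxia in the mean log2 level of the list, with an SD of at most 0.13 within a group, but this gap restates that the groups do not overlap in the called genes and decides nothing. A real lowering of these genes at 96 h of low oxygen stays open too and was not tested.

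Of the 59 skeletal muscle rows, 18 rose and none fell in the libraries labelled hypoxia, while over the list alone 39 were higher and 5 lower (Mb, tpm2, myoz2b, ldb3a MSTRG.31056 and ttn.1 MSTRG.29008), with an adjusted p = 0.360 with an estimated correlation. Scaling does not account for the 18, since all of them stayed higher past the threshold after quantile normalization. More arch muscle in the dissected pieces stays open: of the 31 muscle rows with a mean of at least 5 FPKM, 6 (myl2b, mybpc1, MYL2, myl1, tnni1a and pgam2) rose past the threshold above the median change of these 31, 0.92, but 5 lay past the threshold below it, and such members lower the median, so the count decides nothing. An earlier form of this test, which counted departures either way from the list mean, gave 12 of 31 muscle rows and 11 of 16 cartilage and bone rows and decides nothing either. The cartilage and bone list and the extracellular matrix list were higher in the same libraries (adjusted p = 0.338 and adjusted p = 0.360 with an estimated correlation), and a different mix of fiber types in the pieces and an effect of the treatment on muscle also stay open and untested.

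Of the called interferon response genes, all 9 were higher in the libraries labelled hypoxia, with a median log2 change of 1.34. All 9 stayed higher past the threshold after quantile normalization, which argues against scaling. An equal rise of all immune cells in the pieces would raise the markers of the T cell, B cell, macrophage and granulocyte lists as much. The upper quartile of those 91 rows was 0.50 and their median 0.13, against a median of 0.83 for the whole interferon list. This argues only against an equal rise of these cell classes. More cells of 1 class stay open, since single markers moved apart (log2 change 1.31 for csf1ra and -1.97 for LECT2). A response to a pathogen in some tanks and an effect of the treatment stay open, since the tank of each library is not known here and could not be entered in a test.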
